A study of Mus musculus with 85 samples.

How the data were processed

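Total RNA of the hippocampus of 85 mice aged 8 months was sequenced, with 1 library per mouse. Per the labels, RNA came from a phenol-chloroform extraction and libraries followed the standard BGI-500 protocol. Each mouse was male or female, was a C57BL/6J control or of the transgenic strain that the labels call AD (AD mice here), and ate a standard or a methionine-restricted feed. The 8 groups were control males on standard feed (MWT, n = 11), AD males on standard feed (MAD, n = 11), control males on restricted feed (MWTMR, n = 10), AD males on restricted feed (MADMR, n = 11), and the same 4 combinations in females (FWT, n = 10; FAD, n = 11; FWTMR, n = 10; FADMR, n = 11). The labels give no litter, batch, cage or sequencing date.

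The deposited values are FPKM, fragments scaled to transcript length and library size, in 1 table with a column per library. Per the submitters' processing notes, the tools were Trimmomatic 0.38, HISAT2 (version not given in the sources used here) and StringTie 1.3.4d, on the mouse genome build GRCm38.p6. Their order and options are not given in the sources used here. Of the 56090 rows in the deposited table, 14100 carry no gene symbol, 1713 name several genes joined in 1 assembled locus, and 26 hold a date where a symbol would be. Rows with an equal symbol were summed (1664 symbols were on more than 1 row), which left 53881, of which 7678 were at 0 in all 85 libraries. A joined locus is written here by the gene of interest and called a locus: the value of the Prnp locus, for example, also holds Prn and Prnd. The mitochondrial genome is joined into 2 such loci, so of the 35 gene lists the list of mitochondrially encoded proteins had too few separate members and was not tested.

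Depth is unknown. FPKM holds no read counts, and low values of a gene were not whole multiples of a common step. Totals of FPKM per library ran from 939248 to 1066927, and rows at 1 FPKM or more from 17973 to 20441. No interval from counting can be given, and precision rests on the spread between mice. No column was identical to another, and the correlation of log2 values between libraries ran from 0.845 to 0.969.

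Here, each library was divided by a median-of-ratios factor (0.876 to 1.10), and rows with at least 1 FPKM in at least 10 libraries were kept. This left 21297 loci: 12547 with the symbol of 1 gene, 1394 naming several genes and 7356 without a symbol. They are called genes in all counts below. Values were analysed as log2(scaled FPKM + 1). A change on this scale understates the change of genes with low FPKM. The model was limma 3.58.1 (R 4.3.3, statmod 1.5.0) with a mean for each of the 8 groups, a mean-variance trend and a robust prior, fitted to all 85 libraries with 77 residual degrees of freedom. From this fit came 14 comparisons: genotype within each sex and feed, feed within each sex and genotype, the 3 effects averaged over the other factors, and the 3 pairwise interactions. P-values are two-sided and adjusted by Benjamini-Hochberg within a comparison, with 0.05 as the threshold. Differences are AD minus control, restricted minus standard and female minus male, followed by their standard error (SE). FPKM means are given with their SD over mice. A count of mice beside an adjusted p is the number of AD or restricted-feed mice past the median of the other group in the direction of the change.

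Gene lists of cell types, of tissues next to the hippocampus and of pathways were tested with limma's camera with the correlation between genes estimated from the residuals, adjusted over 34 lists in 14 comparisons (476 tests). Membership of a list is tested against all other genes. With a preset correlation of 0.01 in its place, 151 of the tests pass, against 10 with the estimate, so list results rest on the estimate throughout. A further test asked whether genes that differ with genotype in 1 sex move the opposite way with feed in AD mice of the other sex, again with camera, where at least 10 genes were available.

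The groups, the model, the filter, the lists, the comparisons and 10 kinds of alternative (pseudocount 0.1, no filter, a filter at 5 FPKM, FPKM as deposited, an equal total per library, no trend, array weights, a replicate block, 4 tissue covariates, and only the groups compared), together with the preset correlation, were fixed before the data were examined. So was the rule for genes named in the text: the 10 largest rises and 10 largest falls among genes past the threshold with a mean of at least 1 FPKM in the higher group, leaving out predicted genes and loci without a symbol, up to 4 members of each described list by smallest p, the 3 smallest p where no gene passes, and always App, Prnp, Xist, Ddx3y, Gfap, Cst7, Trem2, Mat2a, Asns, Fgf21 and Ttr. Some genes that the rule picks are not reported here, though they count in all numbers of genes and in the list tests. Alternatives added after seeing the data left out each library in turn, kept rows of an equal symbol apart, used only loci with a symbol, or added as a covariate the score on the main axis of variation within groups.

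Positions are RefSeq's on GRCm38.p6, matched by symbol; 36515 of the 39755 named rows had one. The model was tested on simulated data for the comparison of AD with control males on standard feed, with 21297 genes: it recovered 9 of 50 genes changed by 0.25 on the log2 scale, 27 of 50 changed by 0.5, 45 of 50 changed by 1 and 50 of 50 changed by 2, and called 1 unchanged gene.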

Results

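Gene expression was measured in the hippocampus of 85 mice of 8 months in 8 groups of 10 or 11. The groups differ in sex, in genotype (control or transgenic AD mice) and in methionine-restricted or standard feed. AD mice of this line carry a mouse App gene with a humanised, mutated segment behind the promoter of the prion protein gene Prnp, and deposit amyloid plaques. Depth is unknown because the values are FPKM. Total FPKM ran from 939248 to 1066927 per library, and the heavy-strand mitochondrial locus took 7.63% to 16.7% of it. The number of rows at 1 FPKM or more was higher in females (19621 ± 266 in FWT, SD, n = 10) than in males (18728 ± 381 in MWT, SD, n = 11).

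The labels were checked with genes known in advance. Xist, the RNA that silences 1 X chromosome in females, was at 100.1 ± 48.7 FPKM in 42 females and at 0.345 ± 0.174 in 43 males (SD). The locus of the Y-linked helicase gene Ddx3y was at 402 ± 109 FPKM in males and at 0.404 ± 0.358 in females. The Prnp locus (chromosome 2, 131909928 to 131938436) was at 1201 ± 151 FPKM in 44 AD mice and at 335 ± 48.0 in 41 control mice (SD), and the lowest AD mouse, at 917, lay above the highest control mouse, at 435. No library went against its label for sex or genotype.

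Averaged over sex and feed, the list of microglia near plaques had the smallest adjusted p of the gene lists between AD and control mice. Ccl3, a chemokine, rose by 1.43 ± 0.090 on the log2 scale, Cst7, a cystatin, by 1.01 ± 0.073, and Trem2, a microglial lipid receptor, by 0.83 ± 0.076. Its signalling partner Tyrobp rose by 0.80 ± 0.066 and the lectin Clec7a by 0.80 ± 0.053. Lilrb4a (0.84 ± 0.064), the lysozyme locus Lyz2 (0.82 ± 0.085), Slc11a1 (0.73 ± 0.068) and Phf11b (0.87 ± 0.14) were also among the 10 largest rises. Of 27 measured members of the list of plaque-associated microglia 18 rose and none fell, among them also Cd68 (0.60 ± 0.047), with 20 higher when adjusted over the list alone (camera, adjusted p = 5.08e-06 with an estimated correlation). Astrocyte activation genes rose as well: Gfap, the intermediate filament of astrocytes, went from 1431 ± 300 FPKM (SD, n = 41) to 2367 ± 620 (SD, n = 44), a log2 difference of 0.71 ± 0.073.

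Other immune lists moved the same way. Of 11 complement and Fc receptor genes 7 rose, including Fcer1g (0.60 ± 0.057), Itgb2 (0.55 ± 0.056), C1qb (0.45 ± 0.059) and Fcgr1 (0.38 ± 0.044), with 9 adjusted over the list alone (adjusted p = 0.000183). Of 13 homeostatic microglia genes 6 rose, with Fcrls at 0.61 ± 0.090, Gpr34 at 0.42 ± 0.075 and the Csf1r locus at 0.25 ± 0.047, and 8 did adjusted over the list alone (adjusted p = 0.00293). Of 18 reactive astrocyte genes 8 rose, with Cd14 (0.43 ± 0.062), Cxcl16 (0.38 ± 0.085) and S100a6 (0.32 ± 0.052) beside Gfap, and the count adjusted over the list alone was also 8 (adjusted p = 0.00344). Cd14 and Cxcl16 are known from myeloid cells as well.

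In 4 further lists single members rose but the list did not pass. Of 18 type I interferon genes 9 rose, such as Ifit3 (0.54 ± 0.12) and Ifit3b (0.42 ± 0.090), with 15 adjusted over the list alone, at adjusted p = 0.175 with an estimated correlation. Of 29 cholesterol and fatty acid synthesis genes 8 rose, among them the enzymes Hmgcs1 (0.23 ± 0.049), Fdft1 (0.22 ± 0.047) and Nsdhl (0.16 ± 0.031), with 10 adjusted over the list alone (adjusted p = 0.142). Of 28 lysosome and autophagy genes 6 rose, with the proteases Ctsz (0.52 ± 0.061), Ctsd (0.37 ± 0.061) and the Ctss locus (0.52 ± 0.065), and 10 did adjusted over the list alone (adjusted p = 0.291). Of 11 antigen presentation genes 3 rose, among them the Cd74 locus (0.51 ± 0.13) and Psmb9 (0.31 ± 0.078), with 7 adjusted over the list alone (adjusted p = 0.133).

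The transgene itself was visible at the Prnp locus (1.84 ± 0.039, adjusted p = 7.07e-56) and at App (0.32 ± 0.045, adjusted p = 3.92e-07), where AD mice had 3512 ± 595 FPKM and control mice 2817 ± 406 (SD). The list of transgene processing genes did not pass as a whole (2 of 12 higher, 4 adjusted over the list alone, adjusted p = 0.102). The largest rise of any locus was in MSTRG.4241, which has no symbol and was picked out after its values were seen (2.11 ± 0.035, adjusted p = 1.1e-63). Falls were smaller. The largest, Pnkd, fell by 0.46 on the log2 scale (SE 0.13, adjusted p = 0.0434), and Wnk4, a kinase gene, fell by 0.38 (SE 0.095). Cort, the gene of the interneuron peptide cortistatin, fell by 0.37 (SE 0.088) and Traip, a ubiquitin ligase gene, by 0.36 (SE 0.070). Ryr1, a calcium release channel gene, fell by 0.35 (SE 0.084), Arpp21, a neuronal phosphoprotein gene, by 0.34 (SE 0.050) and Nsmf by 0.31 (SE 0.091, adjusted p = 0.0493). Dio2, which activates thyroid hormone, Noxred1 and Cfap100 fell by 0.30 (SE 0.080), 0.30 (SE 0.070) and 0.29 (SE 0.073).

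In limma's test, 370 of 21297 genes passed in this average, 261 higher and 109 lower in AD mice. Single members were called in 5 lists that did not pass: Sox9 of the astrocytes (0.15 ± 0.040, adjusted p of the list 0.914), Drd1 of the striatum (0.29 ± 0.059, list 0.756), Tst of transsulfuration (0.18 ± 0.052, list 0.868), Igf1 of FGF21 and insulin-like growth factor signalling (0.14 ± 0.028, list 0.811) and, downward, Sesn2 of the ATF4 targets (-0.22 ± 0.060, list 0.852). No member was called in the other 20 lists, whose adjusted p ran from 0.557 for the glucocorticoid response to 0.969. The count was 186 with marker means of choroid plexus, thalamus, striatum and meninges as covariates, which ended the calls of Pnkd, Wnk4, Nsmf, Noxred1, Dio2, Cfap100, Sox9, Drd1, Tst and Sesn2 but of no other gene named above for this average. Drd1 is itself part of the striatum mean, so the end of its call is partly built in. Pnkd, Nsmf, Tst and Sesn2 were also lost without 34, 53, 28 and 13 of the libraries left out in turn.

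**Figure D1:**
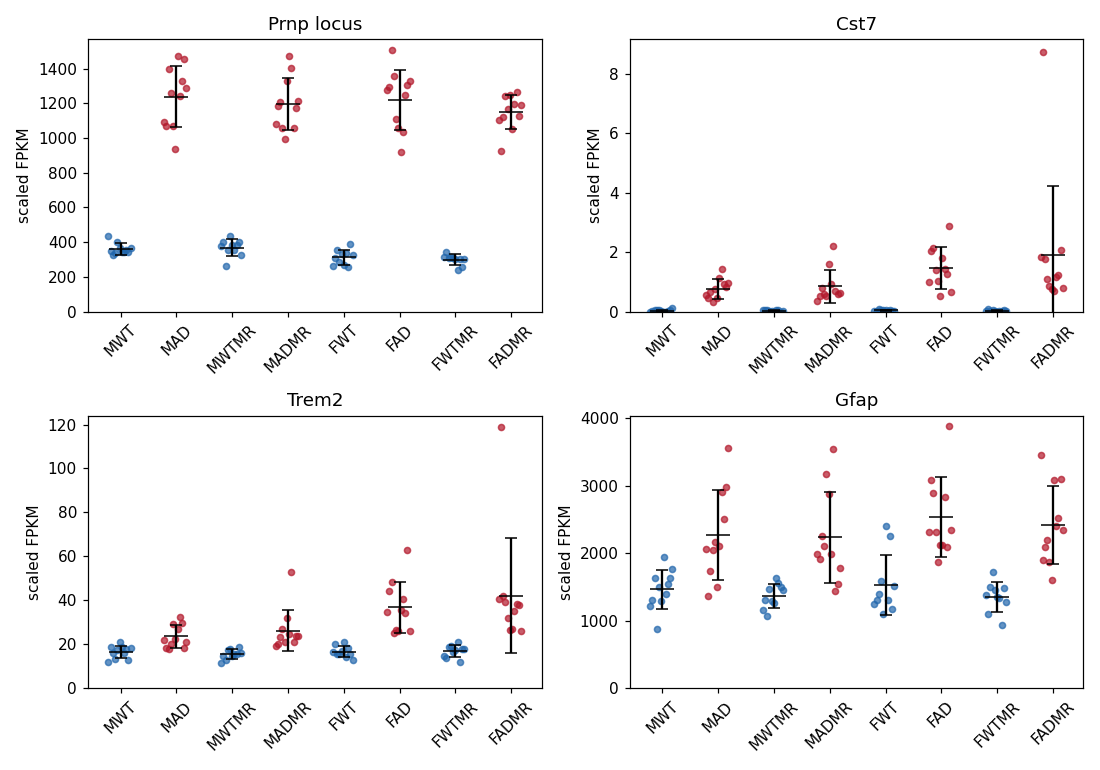
Scaled FPKM (vertical axes, linear) of the Prnp locus, Cst7, Trem2 and Gfap in each of the 85 libraries, by group; points are mice (blue control, red AD), horizontal bars the mean and vertical bars the SD, that of Cst7 in FADMR reaching below the axis. All AD mice lie above all control mice at the Prnp locus, and 1 FADMR mouse (replicate 10) stands apart at 8.73 for Cst7 and 119 for Trem2.

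Among females on standard feed, 110 genes differed between AD and control mice, 67 higher and 43 lower. Ccl3 rose by 1.77 ± 0.18 (adjusted p = 2.42e-11), Cst7 by 1.19 ± 0.15 (adjusted p = 2.43e-08), Tyrobp by 1.05 ± 0.13 (adjusted p = 4.57e-08), Trem2 by 1.05 ± 0.15 (adjusted p = 2.61e-06) and the Ly86 locus by 0.93 ± 0.12 (adjusted p = 8.12e-08). Each was higher in 11 of 11 AD mice. Clec7a (0.89 ± 0.11), Lilrb4a (0.87 ± 0.13), the Lyz2 locus (0.86 ± 0.17), Cd68 (0.76 ± 0.094), Gfap (0.75 ± 0.15) and the complement gene C1qa (0.61 ± 0.13) rose too. Hnrnph2, an RNA-binding protein gene, was higher by 0.93 ± 0.24 (adjusted p = 0.0469, 10 of 11 mice) and App by 0.36 ± 0.091 (adjusted p = 0.0367, 10 of 11 mice). Arc, an immediate early gene of neurons, fell by 1.07 on the log2 scale (SE 0.21, adjusted p = 0.00221, 11 of 11 mice), from 20.9 ± 3.43 FPKM (SD, n = 10) to 9.52 ± 2.23 (SD, n = 11). Smaller falls were those of Zglp1 (-0.42 ± 0.094, adjusted p = 0.0106), Arpp21 (-0.39 ± 0.10, adjusted p = 0.0461) and Tbc1d2 (-0.30 ± 0.077, adjusted p = 0.0469).

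The lists of plaque-associated microglia (adjusted p = 0.00139) and of complement and Fc receptors (adjusted p = 0.024) passed in these females. The complement result was lost with the tissue covariates and without 3 of the libraries in turn, where its adjusted p ran from 0.00954 to 0.0684, the latter without FAD replicate 5. With array weights 337 genes were higher and 1005 lower, and with loci that have a symbol alone 64 were higher and 7 lower. The count of genes depended on single mice: 604 without FAD replicate 5, of which 471 were lower, and 63 without FWT replicate 1, 64 without FAD replicate 8 or 11, 67 without FAD replicate 2, 68 without FAD replicate 7, 72 without FWT replicate 2 and 73 without FAD replicate 10. The calls of Hnrnph2, App, Arpp21 and Tbc1d2 were lost without 28, 13, 14 and 20 of the libraries and with the tissue covariates, under which 63 genes were called.

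Among females on restricted feed, 293 genes differed with genotype, 200 higher and 93 lower. The same kinds of genes led: Ccl3 (1.34 ± 0.18, adjusted p = 2.61e-07), Phf11b (1.28 ± 0.28, adjusted p = 0.00359), Cst7 (1.28 ± 0.15, adjusted p = 1.42e-09), Tyrobp (1.17 ± 0.13, adjusted p = 1.25e-09), Trem2 (1.15 ± 0.15, adjusted p = 1.32e-07), Fcrls (1.10 ± 0.18, adjusted p = 2.79e-05) and the Lyz2 locus (1.08 ± 0.17, adjusted p = 1.54e-05), each in 11 of 11 AD mice. Lilrb4a (1.04 ± 0.13), the Cd74 locus (1.06 ± 0.27, adjusted p = 0.0197), Gpr34 (0.76 ± 0.15), C1qb (0.71 ± 0.12), Cd14 (0.61 ± 0.13), Xaf1 (0.54 ± 0.12), S100a6 (0.52 ± 0.11) and the lysosomal gene Grn (0.43 ± 0.087) rose as well. Sds, which breaks down serine, fell by 1.03 on the log2 scale (SE 0.25, adjusted p = 0.0129, 10 of 11 mice), Myl1 by 0.68 (SE 0.16, adjusted p = 0.00704) and the cell adhesion gene Dscaml1 by 0.43 (SE 0.073, adjusted p = 6.34e-05). Other falls were Nanos2 (-0.68 ± 0.19), Npr1 (-0.65 ± 0.16), a natriuretic peptide receptor gene, Traip (-0.56 ± 0.14), the Kirrel3os locus (-0.49 ± 0.13), the Zfp811 locus (-0.47 ± 0.11), Foxo6 (-0.45 ± 0.13, 8 of 11 mice) and Zxdc (-0.38 ± 0.10), with adjusted p from 0.011 to 0.0456.

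Plaque-associated microglia (adjusted p = 0.000747), complement and Fc receptors (0.000925) and homeostatic microglia (0.00487) passed as lists. With FPKM as deposited the split was 150 higher and 117 lower. The count was 93 with the tissue covariates and 189 without FADMR replicate 10, the mouse with the highest Cst7 and Trem2, where the calls of the Cd74 locus, Npr1 and Traip were lost. With the tissue covariates Phf11b, the Cd74 locus, Sds, Cd14, Xaf1, Nanos2, Npr1, Traip, the Kirrel3os locus and Foxo6 were lost, and without 12, 11, 13 and 9 of the libraries Nanos2, the Kirrel3os locus, Foxo6 and Zxdc.

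Males showed fewer calls. On standard feed 13 genes differed with genotype, 11 higher and 2 lower: the Prnp locus (1.77 ± 0.076), Ccl3 (1.14 ± 0.18, adjusted p = 4.37e-05), Cst7 (0.75 ± 0.14, adjusted p = 0.00582), Clec7a (0.67 ± 0.10, adjusted p = 4.37e-05) and Slc11a1, a metal transporter gene of phagocytes (0.65 ± 0.13, adjusted p = 0.0149), were higher in 11 of 11 AD mice each. Sox9 was higher by 0.35 ± 0.078 (adjusted p = 0.0474, 11 of 11 mice). Trem2 (0.47 ± 0.15, adjusted p = 0.354), Gfap (0.60 ± 0.14, adjusted p = 0.0736) and App (0.33 ± 0.088, adjusted p = 0.181) did not pass. On restricted feed 24 genes differed, 20 higher and 4 lower. Ccl3 (1.48 ± 0.18, adjusted p = 3.09e-08), Lilrb4a (0.82 ± 0.13, adjusted p = 4.33e-05), Cst7 (0.81 ± 0.15, adjusted p = 0.00169), Trem2 (0.67 ± 0.15, adjusted p = 0.0375), Gfap (0.66 ± 0.15, adjusted p = 0.0298), and Cd52 (0.61 ± 0.12, adjusted p = 0.00557) rose, each in 11 of 11 AD mice. So did the Lyz2 locus (0.78 ± 0.17), Tyrobp (0.60 ± 0.13), Slc11a1 (0.60 ± 0.14) and the Ly86 locus (0.58 ± 0.12), with adjusted p from 0.0138 to 0.0376. Btbd6 (-0.43 ± 0.099), Map3k19 (-0.40 ± 0.091), Narf (-0.34 ± 0.080) and Cc2d1a (-0.22 ± 0.050) fell, with adjusted p from 0.0362 to 0.0463.

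No list passed in males. Plaque-associated microglia had adjusted p = 0.074 on standard feed and the lowest value on restricted feed was 0.102. On standard feed the count was 34 without MWT replicate 1 and 23 without MAD replicate 10, and Slc11a1 and Sox9 were lost without 1 (MWT replicate 3) and 52 libraries. On restricted feed it was 11 without MWTMR replicate 10, 14 without MWTMR replicate 4 and 12 without MADMR replicate 4, and Trem2, Gfap, Tyrobp, Slc11a1 and the Lyz2 locus were lost without 9, 8, 8, 15 and 4 libraries. Narf, Cc2d1a, Btbd6 and Map3k19 were lost without 38, 14, 12 and 11, and with FPKM as deposited 22 genes were higher, 0 were lower and all 4 falls were lost.

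Part of the called genes were shared between comparisons that have no library in common. On restricted feed, 16 genes rose with genotype in both sexes, where independent lists would share 0.188, and on standard feed 7 did, where 0.0346 would be shared. On either feed 0 genes fell in both sexes. Over all genes the genotype differences of the sexes correlated at -0.033 on standard and 0.015 on restricted feed (Pearson). Of the genes called in females on these feeds, 64 of 110 and 228 of 293 had the same direction in males. Of those called in males, 8 of 13 and 24 of 24 had it in females. In females 52 genes rose on both feeds (0.629 if independent) and 0 fell on both (0.188 if independent). In males 7 rose on both feeds (0.0103 if independent). The Prnp locus, where the transgene itself is visible, was not left out of the counts of shared rises, so part of each follows from the construct.

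**Figure D2:**
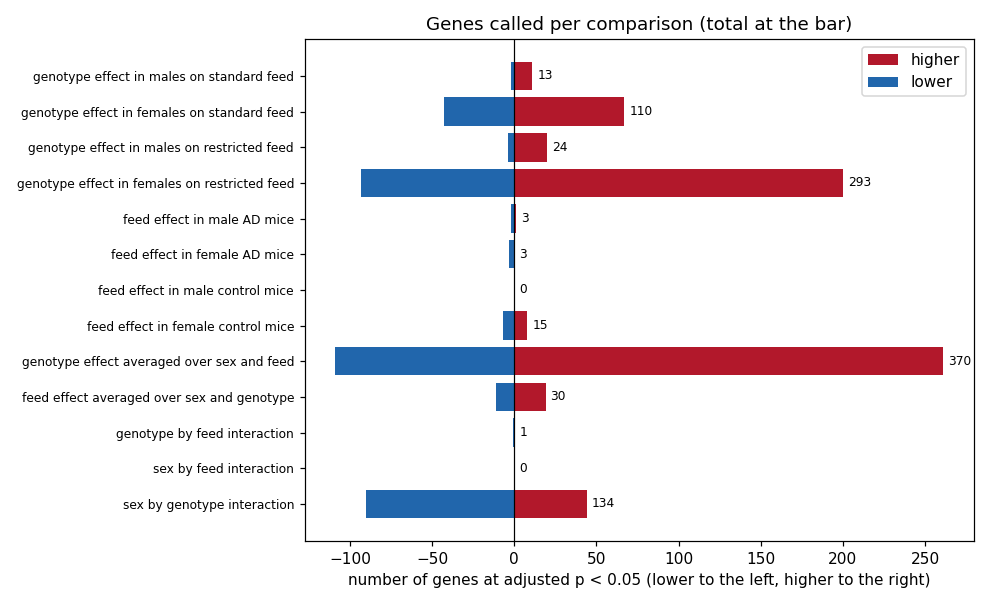
Number of genes past an adjusted p of 0.05 in 13 of the 14 comparisons (limma; red bars to the right are higher, blue bars to the left lower, the total stands at the bar); the comparison of the sexes, with 10747, is left out for scale. Genotype gives 370 genes in the average over groups and feed gives 30.

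Few genes differed between the feeds. Averaged over sex and genotype 30 passed, 19 higher and 11 lower on restricted feed. Tmem194b had the smallest adjusted p (0.20 ± 0.034, adjusted p = 0.00196), and Slc6a6, the taurine transporter gene, rose in this average by 0.22 ± 0.050 (adjusted p = 0.0399). Its FPKM on standard and restricted feed were 34.5 ± 10.0 and 42.4 ± 6.11 in control males (SD, n = 11 and 10) and 38.9 ± 8.55 and 43.7 ± 4.64 in AD males (n = 11 and 11). They were 30.1 ± 4.47 and 34.6 ± 3.32 in control females (n = 10 and 10) and 32.7 ± 6.58 and 36.2 ± 3.72 in AD females (n = 11 and 11). Other rises were those of Btla (0.32 ± 0.076), an inhibitory receptor of lymphocytes, the Reck locus (0.21 ± 0.047), Pus10 (0.21 ± 0.045), Fnbp4 (0.21 ± 0.049), Odf2 (0.16 ± 0.035), Gzmm (0.15 ± 0.032) and Guf1 (0.14 ± 0.033). Tnfrsf25, a death receptor gene, fell by 0.58 on the log2 scale (SE 0.11, adjusted p = 0.0119), Noxred1 by 0.32 (SE 0.070), Zglp1 by 0.20 (SE 0.047), Fam46a by 0.19 (SE 0.043), Tbc1d2 by 0.19 (SE 0.038) and Taf12 by 0.13 (SE 0.028).

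Gene groups tied to methionine did not pass. Of 29 genes of methionine and one-carbon metabolism none was called (median log2 difference -0.003, adjusted p = 0.946), and Mat2a, which makes S-adenosylmethionine, had 0.10 ± 0.093 (adjusted p = 0.901). Of 17 transsulfuration and hydrogen sulfide genes 1 rose, Slc6a6 (adjusted p = 0.944). Of 31 ATF4 targets of the amino acid response none was called (adjusted p = 0.977), with Asns at 0.05 ± 0.041 (adjusted p = 0.866). Among FGF21 and insulin-like growth factor genes none was called (adjusted p = 0.969), and Fgf21 itself was below the filter and not tested. The immediate early genes had the lowest median of these lists, -0.15, with none of 24 called over all genes and 5 lower when adjusted over the list alone (adjusted p = 0.421 with an estimated correlation). The lists of mitochondrial biogenesis (0.937), the nuclear respiratory chain (0.868), NRF2 and antioxidant enzymes (0.977), plaque-associated microglia (0.914) and reactive astrocytes (0.962) did not pass either, nor did any other, the smallest adjusted p being 0.25 for the striatum list.

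In this average, 1602 genes had an unadjusted p under 0.05, where 1065 would by chance. The count of 30 became 5 with the tissue covariates, 12 with the replicate number as a block, 14 with the stricter filter, 66 without MWT replicate 1 and 48 without MAD replicate 8, and an equal total per library gave 34 higher and 9 lower. The calls of Slc6a6, Btla, Fnbp4, Guf1 and Zglp1 were lost without 43, 49, 50, 39 and 30 of the libraries, and only Tmem194b, Gzmm and Fam46a of the genes named were still called with the tissue covariates.

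Within the groups still fewer genes differed between the feeds. In AD males 3 were called: Sgk1, a glucocorticoid-induced kinase gene, fell by 0.88 on the log2 scale (SE 0.17, adjusted p = 0.0254, 11 of 11 mice), from 183 ± 40.6 to 99.98 ± 26.6 FPKM (SD, n = 11 each), and, named after their values were seen, 8430408G22Rik fell by 0.56 (SE 0.12, adjusted p = 0.0493) and MSTRG.5593 rose by 0.43 (SE 0.081, adjusted p = 0.0227). In AD females the Ipo7 locus fell by 1.79 (SE 0.35, adjusted p = 0.0287, 10 of 11 mice) and Banp by 0.43 (SE 0.090, adjusted p = 0.0496, 10 of 11 mice). The third gene, MSTRG.18154, named after its values were seen, fell by 0.44 (SE 0.087, adjusted p = 0.0287). In control females 15 genes were called, 8 higher and 7 lower, with falls of Tnfrsf25 (-1.18 ± 0.23, adjusted p = 0.00733), Zglp1 (-0.52 ± 0.097, adjusted p = 0.00592), Tbc1d2 (-0.35 ± 0.079, adjusted p = 0.0395) and Nadsyn1 (-0.23 ± 0.047, adjusted p = 0.0207) and rises of Lcmt2 (0.36 ± 0.076, adjusted p = 0.0207) and Lyl1 (0.35 ± 0.079, adjusted p = 0.0497), each in 10 of 10 mice. In control males limma called 0 genes, with 1436 at an unadjusted p under 0.05, and the smallest p among named genes belonged to Riok3 (0.25 ± 0.051, adjusted p = 0.0982), Ints6 (0.85 ± 0.19, adjusted p = 0.129) and Pde10a (0.41 ± 0.091, adjusted p = 0.129).

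No list passed in these 4 comparisons, the smallest adjusted p being 0.102, for hippocampal excitatory neurons in AD females. Single libraries decided these counts. In control males 76 genes were called without MWT replicate 1, 4 without MWTMR replicate 1, 3 without MWTMR replicate 7 and 1 without MADMR replicate 3. In AD males the count ran from 0 (without MAD replicate 9 or 11 or MADMR replicate 10) to 8 (without MAD replicate 8) and in AD females from 0 (without FAD replicate 1, 2, 3, 4, 6 or 8 or FADMR replicate 1, 8 or 10) to 6 (without FAD replicate 11 or FADMR replicate 9). In control females it was 7, 8, 9 and 9 without FWTMR replicate 5, 2 and 7 and FWT replicate 7, and 25 and 28 without FWTMR replicate 9 and 10. In AD males FPKM as deposited gave 2 higher and 0 lower and ended the call of Sgk1. Sgk1 was lost without 8 libraries, the Ipo7 locus without 10 and Banp without 52. Lcmt2, Lyl1, Tbc1d2 and Nadsyn1 were lost without 4, 56, 13 and 5, while Tnfrsf25 and Zglp1 in control females kept their call without any 1 of the 85.

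Whether the feed moved genotype genes back was tested across the sexes, so that no library served to pick and to test genes. The 67 genes higher with genotype in females had a median feed difference of 0.05 in AD males (p = 0.377, adjusted p = 0.377), with 22 of them lower. The 43 genes lower with genotype in females had a median of -0.12 there (p = 0.154, adjusted p = 0.231), with 13 of them higher. The 11 genes higher with genotype in males had a median of 0.10 in AD females (p = 0.0809, adjusted p = 0.231), with 1 of them lower. The 2 genes lower with genotype in males were too few. None of these 3 medians lay in the direction opposite to the genotype difference of the sex that served to pick the genes. Feed can reverse a genotype difference only where the tested sex has one. Of the 110 genes called in females on standard feed 64 had the same direction in males. The 67 higher genes had a median genotype difference of 0.206 in males on standard feed, and the 11 genes one of 0.871 in females. For the 43 lower genes no such median was taken. Each fit without 1 library picked its genes anew, so these fits test other sets of genes. The second test depended on the genes picked. FWT and FAD mice are not in its comparison, but leaving out FWT replicate 1, 2, 3, 4 or 10 or FAD replicate 2, 7, 8, 10 or 11 left 13 to 25 lower genes. Its unadjusted p was then 0.00195 to 0.0491, with medians down to -0.28, and adjusted over the tests of the same fit it passed without 6 of these 10 mice. Without FAD replicate 5, 471 lower genes were picked, with a median of -0.01. The first median turned to -0.00141, over 71 genes, without MADMR replicate 6 (p = 0.788). The third had an unadjusted p from 0.00995 without MADMR replicate 3 to 0.468 without FADMR replicate 10, and was under 0.05 also without MWT replicate 10, MAD replicate 8 or 12, MADMR replicate 6 or FADMR replicate 3, 4 or 5. Adjusted, it passed without MADMR replicate 3 alone (adjusted p = 0.0298).

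The interactions asked whether the effects differ between groups. Genotype by feed gave 1 gene, Dscaml1, with a difference of -0.39 ± 0.072 (adjusted p = 0.0189): it was at 50.9 ± 4.14 FPKM in FWTMR (SD, n = 10) and 38.2 ± 7.13 in FADMR (SD, n = 11), against 40.8 ± 3.63 in FWT (n = 10) and 43.7 ± 4.09 in FAD (n = 11). In males it was at 45.8 ± 4.25 in MWTMR (n = 10) and 37.3 ± 3.74 in MADMR (n = 11), against 41.4 ± 4.31 in MWT and 40.2 ± 4.44 in MAD (n = 11 each). With FPKM as deposited, or an equal total per library, limma called 0 genes. Sex by feed gave 0 genes in limma, with 1875 at an unadjusted p under 0.05, and BC029214 (0.34 ± 0.073), Cbfa2t3 (-2.31 ± 0.51) and Gadd45gip1 (0.29 ± 0.066) had the smallest p of named genes, all at adjusted p = 0.101.

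Sex by genotype gave 134 genes, 44 with a higher genotype difference in females and 90 with a lower one, of which 83 have no symbol. Among the former were Tyrobp by 0.62 ± 0.13 (adjusted p = 0.0271), Tlr13 by 0.60 ± 0.15, Bin2 by 0.49 ± 0.13, the Ly86 locus by 0.49 ± 0.12, Was by 0.47 ± 0.13, Cd68 by 0.38 ± 0.094 and Tmem119 by 0.37 ± 0.094, where the last 6 had adjusted p from 0.0446 to 0.0495. Trem2 (0.53 ± 0.15, adjusted p = 0.0616) and Cst7 (0.46 ± 0.15, adjusted p = 0.0792) did not pass, and no list did, the smallest adjusted p being 0.301 for complement and Fc receptors. Arc (-0.82 ± 0.21, adjusted p = 0.0462), Zfp281 (-0.35 ± 0.077, adjusted p = 0.0372) and Sox9 (-0.35 ± 0.080, adjusted p = 0.0446) went the other way. This result was not stable: leaving out 1 library at a time gave from 0 genes (without FWT replicate 2) to 1520 (without FAD replicate 5), moved the count by over 1.5 times for 63 of the 85 libraries, and ended the call of each of these named genes for at least 1 library. With the tissue covariates 4 genes were called, with the block 0, with FPKM as deposited 33 were higher and 209 lower, and with loci that have a symbol alone 8 genes were called.

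Females and males differed in 10747 of 21297 genes, 5840 higher and 4907 lower in females. Beyond Xist (6.02 ± 0.14) and the Y-linked genes Eif2s3y (-9.89 ± 0.032), Ddx3y (-8.15 ± 0.085), Kdm5d (-5.14 ± 0.051) and Uty (-3.42 ± 0.042), most differences were small, with a median size of 0.19 among 5779 autosomal calls, 11 of them over 2-fold. Higher in females were the growth factor gene Igf2 (0.84 ± 0.15), Gapdh (0.71 ± 0.16), the haemoglobin locus Hba-a1 (0.66 ± 0.090), the Mid1 locus (0.63 ± 0.10), the tubulin gene Tubb5 (0.63 ± 0.17), Gps2 (0.64 ± 0.26), the Baiap3 locus (0.60 ± 0.17), Auts2 (0.60 ± 0.18) and Mgp of the meningeal list (0.46 ± 0.096). Lower were Gpr63 (-2.02 ± 0.48), Kcna2, a potassium channel gene (-1.75 ± 0.38), Islr2 (-1.71 ± 0.39), Plekha6 (-1.63 ± 0.46), Stard13 (-1.45 ± 0.39) and Eno1b (-1.28 ± 0.36). Lower as well were the list members Nptx1 (-1.04 ± 0.24), Cnr1 (-0.54 ± 0.080), Grin2a (-0.48 ± 0.077) and Dusp6 (-0.43 ± 0.071). App (-0.22 ± 0.045) was lower in females, and Trem2 (0.32 ± 0.076) was higher in this average, mostly through AD mice. In control mice Trem2 was at 16.6 ± 2.84 FPKM in MWT and 16.71 ± 2.51 in FWT, and at 15.58 ± 2.26 in MWTMR and 16.9 ± 2.72 in FWTMR (SD). In AD mice it was at 23.56 ± 5.16 in MAD and 36.75 ± 11.73 in FAD, and at 26.24 ± 9.46 in MADMR and 42.19 ± 26.03 in FADMR, where the highest mouse was at 118.7. With the axis covariate named below, Gpr63, Plekha6, Stard13, Eno1b, Gps2, the Baiap3 locus and App lost their call. Gps2 was also lost without 9 libraries.

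Of 76 cytosolic ribosomal protein genes 40 were higher in females and 4 lower (41 and 4 adjusted over the list alone, adjusted p = 0.859 with an estimated correlation), and of 73 nuclear respiratory chain genes 35 were higher and 6 lower (36 and 6 adjusted over the list alone, adjusted p = 0.852). Of 33 synaptic genes 14 were lower and 2 higher (the same counts adjusted over the list alone, adjusted p = 0.557), and of 24 immediate early genes 11 were lower (11 adjusted over the list alone, adjusted p = 0.725). Of 15 meningeal and fibroblast genes 5 were higher (5 adjusted over the list alone, adjusted p = 0.868). Only the 9 sex chromosome genes passed as a list (4 higher and 4 lower, also adjusted over the list alone, adjusted p = 0.00543, direction down, with a median of -0.01 and a mean of -2.19).

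Loci without a symbol were mostly higher in females, 4136 against 434 lower, and loci of 1 gene mostly lower, 4051 against 1528 higher. Across the 5160 called loci of 1 gene with a known transcript, the difference between the sexes ranked with the length of the longest transcript (Spearman's rho = -0.51, across genes, which are not independent replicates). The labels give no batch by which sex could be compared within. With FPKM as deposited 7177 were higher and 3260 lower, and with the score on the main axis of variation within groups as a covariate 4202 genes were called.

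**Figure D3:**
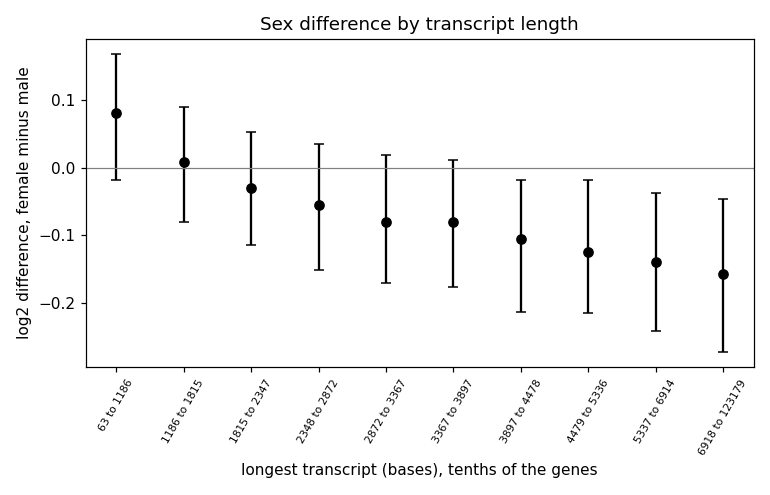
Difference between females and males (vertical axis, log2, female minus male) for 11617 loci of 1 gene in 10 bins by the length of their longest annotated transcript (horizontal axis, bases); points are medians and bars run from the first to the third quartile. The median falls from 0.08 in the bin of the shortest to -0.16 in that of the longest.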

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

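The splits of the samples, except those for the averaged genotype and feed effects, were chosen only after the results were seen. The tests of the axis of variation and of gene length between the sexes were written before their own values were seen, but after females and males had been seen to separate on the first component and short ribosomal and respiratory genes to be higher in females.

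Sex by genotype was singled out because the genotype difference itself differs between the sexes in 134 genes. The genes named by the rule or by a list are Tyrobp 0.624, Tlr13 0.598, AA387883 0.561, Zbtb40 0.512, Sesn3 0.495, the Bin2 locus 0.492, the Ly86 locus 0.491, Was 0.472, Antxr2 0.451, Sdf2l1 0.446, Pdia6 0.391, Cd68 0.376, Tmem119 0.374 and the Psenen locus 0.238. Lower in the female than in the male genotype difference were Arc -0.821, Twistnb -0.407, Zfp281 -0.348 and Sox9 -0.346. In 2 of 100 splits of genotype the count was as large as 134, the real split included, and another split gave 3303, which points to a structure of the samples beyond the groups. Leaving out 1 library at a time gave 0 (without FWT replicate 2) to 1520 genes (without FAD replicate 5). Genotype by feed gave 1 gene, Dscaml1 at -0.385; 4 of 100 splits gave at least as many, and the highest other split gave 1. Sex by feed gave 0 genes in limma, with 1875 at an unadjusted p under 0.05, so all 100 of its splits gave as many, the highest other giving 2.

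In groups of exactly 10 mice, 5 of 33 group and gene pairs held a mouse far from the others, where chance gives about 1 in 20 for normally distributed values. These were Ddx3y at 1.247 FPKM in FWT replicate 10 and at 1.379 in FWTMR replicate 2, Cst7 at 0.08206 in FWTMR replicate 10, Fgf21 at 0.0779 in FWT replicate 11 and Ttr at 839.2 in MWTMR replicate 1. The values of Ddx3y, Cst7 and Fgf21 are near the floor of their gene. Groups of 11 mice, among them all AD groups, were not screened. Values there such as Mat2a at 59.26 in MADMR replicate 4 and at 23.62 in FADMR replicate 4 are outside this count.

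For the genotype effects the splits argue against chance, down to the 1 in 100 that 100 splits can show. The count of the average includes the transgene's own loci, Prnp and App. Averaged over sex and feed 1 of 100 gave at least 370 genes, the real one, and the highest other gave 1. Of males on standard feed (13 genes) and on restricted feed (24), and of females on standard feed (110) and on restricted feed (293), 1 of 100 splits gave as many in each case, the highest others giving 3, 12, 2 and 8. For the feed averaged over sex and genotype 1 of 100 gave at least 30 genes, the highest other giving 1, and in control females 1 of 100 gave at least 15, the highest other giving 2. In AD males 5 of 100 splits gave at least 3 genes, so chance cannot be excluded, and the highest other gave 80. In AD females 3 of 100 gave at least 3, the highest other giving 360; 80 and 360 point to a structure of the samples. In control males limma called 0 genes (1436 at an unadjusted p under 0.05), and all 100 splits gave as many, the highest other giving 1. Between the sexes 1 of 100 gave at least 10747 genes, the highest other giving 2.

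The first pattern is the difference between genotypes in 370 genes. A strain segment carried along with the transgene would gather called genes on a stretch of a chromosome. Of the 370 called genes 322 had a position, and 320 entered the test, which left out transgene loci such as App and Prnp. In Fisher's test 0 of 268 windows of 20 Mb had an odds ratio over 5 at an adjusted p under 0.05. The largest odds ratio was 6.28, on chromosome 16 from 60000001 to 80000000, with 3 of 23 genes called (unadjusted p = 0.0161). This argues against a single segment as the cause of the pattern as a set. Differences between the strains that are spread over many chromosomes would gather in no window and were not tested. A variant next to a single gene stays open as well. With 4 tissue covariates 177 of the 370 stayed called, the median size went from 0.232 to 0.19 (SE 0.052 and 0.051) and 370 of 370 kept their direction, so part of the pattern may move with the tissue taken. The genotype itself, named by the design, stays open as the biological explanation, as a hypothesis.

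The second pattern is the difference between feeds in 30 genes. Tissue next to the hippocampus in the dissection was tested with marker means of 4 tissues as covariates, and 3 of the 30 genes stayed called, fewer than the limit of 0.5 of the genes set beforehand, which by that limit speaks for tissue as a cause. A second criterion, added only after this result was seen, looked at size: the median size was 0.211 without and 0.199 with the covariates, the median SE 0.049 and 0.051, and 30 of 30 genes kept their direction. Why the calls ended was not tested. The count of called genes also fell with the replicate block and with the stricter filter, so a loss of calls is not particular to the tissue covariates. As lists, the marker genes of the 4 tissues did not pass between the feeds (camera, smallest adjusted p = 0.25). The 2 readings conflict, so tissue and feed cannot be told apart for these genes, and the feed may act on them or tissue may differ with the feed.

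The third pattern is the difference between the sexes in 10747 genes. An axis of variation that also separates libraries within a group may account for a large part. With its score as a covariate 3227 of the 10747 stayed called, and the median size of the differences went from 0.226 to 0.088 with SE 0.057 and 0.048. The score still holds the difference between the sexes, with means of -12.09 in males and 12.38 in females (SD 24.19 and 25.18). Part of the loss is therefore built in, whatever the cause of that difference. Its loading correlated with the difference between the sexes at 0.657 across 21297 genes, and gene length is a candidate explanation for its direction in named genes, with Spearman's rho of -0.512 over 5160 called loci of 1 gene (median longest transcript 1692 bases where higher in females and 4061 where lower). The axis was taken from deviations from the group means, and each group is of a single sex. A difference shared by all mice of a sex is thus removed beforehand and cannot itself give the axis. Why the sexes differ along the axis was not tested. Fragmentation of RNA, library preparation in separate runs and a real difference between the sexes stay open for this, as the labels hold no batch.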

How the results depend on the processing

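The fits without single libraries, with the axis covariate, with equal symbols kept apart and with loci that have a symbol only were chosen after the data were seen; the others were planned. For 340 results on named genes, 4767 alternative values kept direction and side of the threshold in 4351 cases, were no longer past it in 394, newly past it in 12 and turned in 10. These were run only for genes that passed or that the naming rule picks, and for the 10 lists that pass. Depth is unknown, so its limit cannot be given. Replicate numbers do not pair the mice: 281 pairs with a shared number had a mean residual correlation of -0.009, from -0.387 to 0.389. Where a value below differs, the cause was not tested, except that the stricter filter and loci with a symbol test fewer genes and that leaving out a library or using only the groups compared uses fewer mice.

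Main counts were 13, 110, 24 and 293 for genotype in males and females on standard feed and in males and females on restricted feed. The stricter filter gave 3, 46 and 138 for males and females on standard feed and females on restricted feed. Array weights gave 40, 1342 (337 higher, 1005 lower) and 700 for males and females on standard feed and males on restricted feed. The block gave 72 and 15 for females on standard and males on restricted feed. The tissue covariates gave 63 and 93 for females on the 2 feeds. The axis covariate gave 52, 43 and 645 for males on the 2 feeds and females on restricted feed. Loci with a symbol gave 71 (64 higher, 7 lower) for females on standard feed, and only the groups compared gave 71, 14 and 194 for females on standard, males on restricted and females on restricted feed. Without FAD replicate 5 females on standard feed had 604, and without FADMR replicate 10 females on restricted feed had 189.

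For feed in AD males (3), array weights gave 35, the block 0 and the axis covariate 34. For AD females (3), no filter gave 0, the stricter filter 1, array weights 0, the tissue covariates 1, the axis covariate 16, only the groups compared 1, without FADMR replicate 10 it was 0 and without FAD replicate 5 it was 1. For control males (0 in limma, 1436 at an unadjusted p under 0.05), array weights gave 228. For control females (15), the stricter filter gave 5, array weights 127, the axis covariate 258 and loci with a symbol 5. For the averaged genotype effect (370), the stricter filter gave 204, array weights 1158, the tissue covariates 186 and the axis covariate 878. For the averaged feed effect (30), the stricter filter gave 14, array weights 209, the block 12, the tissue covariates 5, the axis covariate 213 and loci with a symbol 10. For sex (10747), the stricter filter gave 6534, the axis covariate 4202 and loci with a symbol 6037.

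Genotype by feed (1) gave 0 with FPKM as deposited and with an equal total per library, 3 with array weights and 5 with the axis covariate. Sex by feed (0) gave 367 with array weights and 28 with the axis covariate. Sex by genotype (134) gave 17 with no filter, 71 with the stricter filter, 242 with FPKM as deposited, 203 with an equal total per library, 2396 with array weights, 0 with the block, 4 with the tissue covariates, 221 without FADMR replicate 10, 1520 without FAD replicate 5, 22 with the axis covariate and 8 with loci with a symbol. The median feed difference in AD males of the 67 genes higher with genotype in females (0.0451) had an unadjusted p under 0.05 with the preset correlation (0.0451, p = 0.001, adjusted p = 0.0015). The preset correlation kept the genes of the main fit, while each other fit picked its genes anew. For genes lower with genotype in females (43 genes, -0.121 in the main fit), such a p came with pseudocount 0.1 (20 genes, -0.34, p = 0.0309, adjusted p = 0.0927), no filter (41 genes, -0.101, p = 0.0425, adjusted p = 0.085), the block (19 genes, -0.175, p = 0.034, adjusted p = 0.051), the tissue covariates (20 genes, -0.3, p = 0.00141, adjusted p = 0.00282), the axis covariate (85 genes, -0.0735, p = 0.0128, adjusted p = 0.0384) and the preset correlation (-0.121, p = 3.14e-07, adjusted p = 9.42e-07), each time in the direction of the genotype difference in females. For genes higher with genotype in males (11 genes, 0.0948 in the main fit), tested in AD females, it came with the block (11 genes, 0.0948, p = 0.0222, adjusted p = 0.051), the axis covariate (37 genes, 0.0801, p = 0.046, adjusted p = 0.069) and the preset correlation (0.0948, p = 0.00548, adjusted p = 0.00548). These p are adjusted over the tests of the same fit. The 10 passing list tests became 16 with the axis covariate and 151 with the preset correlation.

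Leaving out each of the 85 libraries in turn gave 9 to 34 and 63 to 604 genes for genotype in males and females on standard feed, and 11 to 32 and 189 to 420 on restricted feed. For feed it gave 0 to 8 in AD males, 0 to 6 in AD females, 0 to 76 in control males and 7 to 28 in control females. The averaged effects ran from 317 to 493 (genotype), 21 to 66 (feed) and 10293 to 11156 (sex), and the interactions stayed at 1 to 1 (genotype by feed) and 0 to 0 (sex by feed) or ran from 0 to 1520 (sex by genotype). The 3 medians, over genes picked anew each time, ran from -0.00141 to 0.0746, from -0.28 to -0.0129 and, in the 79 cases with enough genes, from 0.0337 to 0.152, and the list tests from 9 to 12. Of named genes that passed, 45 of 50 did so without any 1 library for the averaged genotype effect, 20 of 25 and 29 of 41 for females on standard and restricted feed, 4 of 6 and 7 of 17 for males, 10 of 15 for the averaged feed effect and 0 of 18 for sex by genotype.

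The 10 turned values belong to results that did not pass. Mat2a turned with equal symbols kept apart, to -0.0264 for genotype and -0.000964 for feed. For feed, Ddx3y turned to 0.0163 with FPKM as deposited, 0.0134 with an equal total per library and 0.00523 with the block. Cst7 turned to -0.0232 with pseudocount 0.1, -0.00985 with array weights and -0.0563 with the tissue covariates, and ran from -0.0291 (without FADMR replicate 10) to 0.0258 (without FAD replicate 5). Trem2 turned to -0.05 with the tissue covariates.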
